A study of Homo sapiens with 12 samples.

How the data were processed

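RNA sequencing counts were deposited for 12 libraries of MCF7, an estrogen receptor-positive epithelial line from human breast cancer. The cell line label gives MCF7, and the sample titles spell it MFC7. Per the labels, the cells carried a stable lentiviral CRISPR construct against CYFIP1, NCKAP1 or PIP5K1A, or a control construct called NC, and had been selected with puromycin for at least 6 days. Each knockout had replicates 1 to 3 and the control had replicates 2 to 4. Total RNA was made into stranded libraries and sequenced as read pairs. The labels do not state whether the replicates came from separate infections, clones or culture days, so every p-value measures only the spread between these samples.

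The deposited table holds raw counts per gene, which the authors made without normalization, for 40414 genes and 12 libraries, with no count column left unused. The submitters' notes name Trim Galore 0.6.9, STAR 2.7.10a, SAMtools 1.15, deepTools and featureCounts from Subread. They name both hg38 and GRCh37.p13. The exon coordinates in the table are those of GRCh38, since 25560 of the 25564 genes that could be named from GENCODE release 29 overlapped their GRCh38 position. The strand setting, the handling of reads that map to several genes and the annotation release are not stated. Genes with a count of 2 were on average 2.15 times as many as genes with a count of 1 in a library (range 2.02 to 2.31), so that the mates of a read pair appear to have been counted separately. Counting error is therefore larger than the totals imply, and the spread between replicates set the error of every test. The total count per library ranged from 36586296 to 44056504, and on average 28363 genes had at least 1 read.

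Genes with too few counts were removed with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 20938 genes. Libraries were scaled by the trimmed mean of M-values, and a robust quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries. The common biological coefficient of variation was 0.0766. Each of 6 contrasts (every knockout against NC and every pair of knockouts) was tested with the two-sided quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were worked back from the F test, as the absolute log2 fold change divided by the square root of F. Expression levels are CPM, computed by edgeR with effective library sizes and given as mean ± SD over n = 3 libraries per group. Log2-CPM values used a prior count of 2.

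Before the data were examined, 24 gene lists with 512 entries were fixed, of which 506 were found in the table. They cover MHC class I and class II antigen presentation, type I interferon-stimulated genes, interferon-gamma response genes, interferon ligands with their receptors and kinases, nucleic acid sensing, NF-kappaB and inflammatory genes, immune checkpoint and NK cell ligands, and p53 targets. They also cover estrogen response, cell cycle and replication, the WAVE and Arp2/3 complexes, phosphoinositide kinases and phosphatases, SRF and YAP targets, epithelial-mesenchymal transition, luminal and basal epithelial genes, the unfolded protein and integrated stress response, hypoxia and glycolysis, and cholesterol biosynthesis. Markers of immune cells, markers of fibroblasts and endothelium, mitochondrially encoded genes and replication-dependent histones completed them. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the 24 lists of a contrast. Camera compares a list with all other genes. The same test with an estimated correlation, and fry, which tests only whether a list's genes move on balance in 1 direction, were alternatives.

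The genes named were also set by a rule fixed before the data were examined. It took the 3 targeted genes, 13 genes of MHC class I and the interferon response, the 8 largest rises and 8 largest falls per knockout against NC and the 4 largest each way between knockouts. These had to pass the threshold, reach a mean log2-CPM of 2 and have all libraries of one group on the same side of all of the other. Up to 4 members per list were taken by smallest adjusted p in the list's majority direction and up to 2 in the other, and the 8 genes with the largest smallest change in all 3 knockouts were added. Genes outside the rule are named as chosen after their values were seen.

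The expected number of genes shared between contrasts was computed as for independent lists. Because the 3 knockouts share the NC libraries, it was also computed from 20 simulations with negative binomial counts and no difference between groups. With 3 NC libraries the control could not be divided into separate controls of at least 2. The model was also tested on negative binomial counts simulated from the NC means, the library sizes and the fitted dispersions, with changes planted. Genes were drawn independently, so that these counts lack any further structure of the deposited libraries. There the model recovered 74.2%, 83.6% and 79.0% of changes of 1 on the log2 scale in the CYFIP1, NCKAP1 and PIP5K1A contrasts. Of changes of 0.5 it recovered 48.5%, 57.1% and 40.6%. False calls were 6.83%, 7.51% and 6.92% of all calls.

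The alternatives fixed before the data were examined were the size factors of DESeq2 1.42.0, its Wald test, no filter, a stricter filter at a mean log2-CPM of 1, a fit of only the 2 groups compared, the replicate number as a block, each library left out, a change of at least 2-fold, camera with an estimated correlation, fry, and lists limited to members at a mean log2-CPM of at least 1. Alternatives added after the data were seen were halved counts, the level of RN7SK as a covariate, NC 4 as the only control, no mitochondrial genes, offsets for GC content and exon length, and protein-coding genes only. Replicate pairs within groups were checked for identity by a chi-square per gene over genes with a summed count of at least 20. Its mean over genes ranged from 3.58 to 22.65 over the 12 pairs, and no pair was identical. Its median over genes was lower, from 1.19 (NC 2 and NC 3) to 2.61 (CYFIP1 knockout 1 and 3). The check finds identical columns and does not show that replicates were separate cultures. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 and drawn with matplotlib 3.10.9. Nothing was left out of the table except genes below the filter.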

Results

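Counts per gene were compared in 12 libraries of MCF7 cells, with 3 libraries each of the CYFIP1, NCKAP1 and PIP5K1A knockouts and 3 of the NC control. CYFIP1 and NCKAP1 encode subunits of the WAVE regulatory complex, which drives branching of actin filaments, and PIP5K1A encodes a kinase that makes the membrane lipid PI(4,5)P2. The labels give the purpose as finding targets that raise MHC class I in breast cancer through the interferon response. Total counts were 44056504, 38237258 and 38742610 in NC 2, 3 and 4, and 40723565, 42666611 and 39199721 in CYFIP1 knockout 1, 2 and 3. They were 40545014, 39753423 and 36586296 in the NCKAP1 knockout and 41952538, 42583200 and 40164531 in the PIP5K1A knockout. The first principal component held 52.1% of the variance and set the PIP5K1A knockout apart. Mitochondrial genes took 6.14% ± 0.189 of counts in NC, 6.18% ± 0.728 in the CYFIP1 knockout, 6.03% ± 0.303 in the NCKAP1 knockout and 7.06% ± 0.432 in the PIP5K1A knockout (SD, n = 3). Ribosomal protein genes took 3.04% ± 0.203, 2.64% ± 0.0836, 2.61% ± 0.0376 and 2.67% ± 0.0282.

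Each targeted gene was lowest in its own knockout, where its transcript remained detectable. CYFIP1 (GRCh38 chromosome 15, 22867052 to 22981063) had 13.1, 11.4 and 11.6 CPM in its own knockout and 61.1, 64.0 and 56.4 CPM in NC, a log2 fold change of -2.33 (SE 0.0722, edgeR adjusted p = 1.75e-18). NCKAP1 (chromosome 2, 182909115 to 183038858) had 16.2, 13.2 and 14.3 CPM against 145, 148 and 129 CPM, a log2 fold change of -3.27 (SE 0.0785, edgeR adjusted p = 2.18e-21). PIP5K1A (chromosome 1, 151197949 to 151249536) had 33.7, 32.9 and 31.7 CPM against 84.4, 82.8 and 78.8 CPM, a log2 fold change of -1.32 (SE 0.0614, edgeR adjusted p = 8.67e-15). CYFIP1 was also higher in the PIP5K1A knockout than in NC, by 0.18 on the log2 scale (SE 0.065, edgeR adjusted p = 0.0386). That call was lost without NC 2 (adjusted p = 0.0847), NC 4 (0.155) or PIP5K1A knockout 1, 2 or 3 (0.0618, 0.151 and 0.0918). RNA counts do not give the protein level or the edited sequence.

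**Figure D1:**
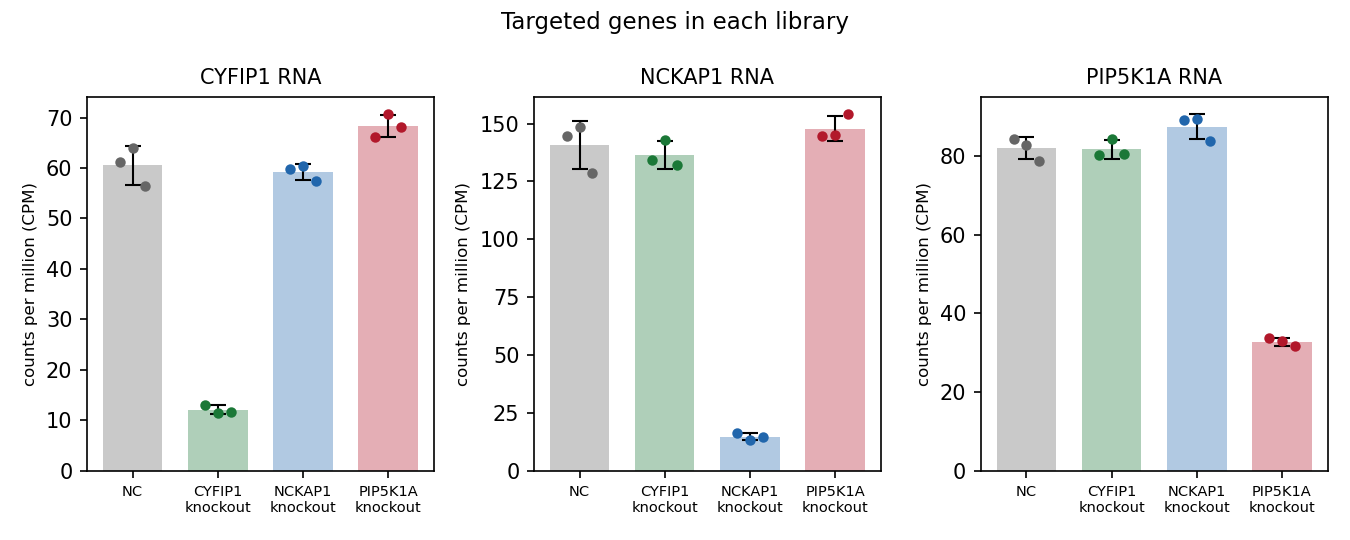
CPM of CYFIP1, NCKAP1 and PIP5K1A in each group, 1 panel per gene (bars, mean; error bars, SD; points, the 3 libraries of a group). Each gene is lowest in its own knockout, at 11.4 to 13.1 CPM for CYFIP1, 13.2 to 16.2 CPM for NCKAP1 and 31.7 to 33.7 CPM for PIP5K1A.

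In the CYFIP1 knockout, genes of the interferon response and of antigen presentation were higher than in NC. TRIM22, an interferon-induced restriction factor, stood at 19.1 ± 4.29 CPM against 6.95 ± 1.06 CPM (SD, n = 3 each), a fold of 2.74. RSAD2, which encodes the antiviral protein viperin, stood at 3.54 ± 0.522 against 1.54 ± 0.266 CPM, and IFIT3, a partner of IFIT1, at 343 ± 31.9 against 179 ± 26.3 CPM. Of 54 type I interferon-stimulated genes measured, 38 rose and none fell (48 and 0 adjusted over the list alone), with a mean log2 fold change of 0.57. Of 22 genes of MHC class I presentation, 6 rose and none fell (14 and 0 adjusted over the list alone), with a mean of 0.41.

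Among genes with an official symbol, a mean log2-CPM of at least 2 and no overlap between the libraries of both groups, as in all rankings that follow, the largest rises were those of TRIM22 (log2 fold change 1.45, SE 0.132, edgeR adjusted p = 1.72e-06), SAMD9L (1.40), MX2 (1.30), RSAD2, whose CPM is given above, APOL6 (1.10), OAS2 (1.03), GBP3 (0.97) and IFIT3 (0.94). OAS2 activates RNase L on double-stranded RNA, MX2 is an antiviral GTPase, and GBP3 is a guanylate-binding protein. In the type I list, IFIT2 rose by 0.87 and OASL by 0.81, ISG15, a ubiquitin-like modifier, by 0.62, MX1 by 0.60, STAT1, the transcription factor of interferon signaling, by 0.38 and OAS1 by 0.33. IFIT1 was higher by 0.33 (edgeR adjusted p = 0.00659), a call lost without NC 2 (0.0719) or NC 3 (0.0901). IRF9, the partner of STAT1 and STAT2, was at 0.02 (0.938). Among 20 interferon-gamma response genes, 10 rose and none fell (16 and 0 adjusted over the list alone; mean 0.69), including APOL1 (0.82) and IRF1 (0.63), a transcription factor induced by interferon-gamma. In the MHC class I list, NLRC5, the transactivator of class I genes, rose by 1.41 (SE 0.239, edgeR adjusted p = 0.00121) and TAP1, a subunit of the peptide transporter, by 0.49 (SE 0.0843). B2M, the class I light chain, stood at 104 ± 5.79 against 86.4 ± 1.58 CPM, a log2 fold change of 0.26 (edgeR adjusted p = 0.0193), lost without NC 2 (0.123), NC 3 (0.0906) or CYFIP1 knockout 1 (0.0524). TAP2 was at 0.43 (0.00701), lost without NC 2 (0.0677) or NC 3 (0.0663). HLA-B was at 1.12 (0.0241), lost without NC 2 (0.067), NC 3 (0.0766), NC 4 (0.0558), CYFIP1 knockout 1 (0.0858) or CYFIP1 knockout 3 (0.117). HLA-A at 0.61 (0.0879; 0.72 and 0.0312 without NC 4) and HLA-C at 0.36 (0.526) did not pass. The HLA genes have near-identical and polymorphic copies, so their counts are uncertain. HLA-A, HLA-B and HLA-C also had only 0.828 to 3.68 CPM as group means.

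Outside these lists, NF-kappaB and inflammatory genes were higher in the CYFIP1 knockout, with 6 of 18 up and none down (12 and 0 adjusted over the list alone; mean 0.47). TNFAIP3, a feedback inhibitor of NF-kappaB, rose by 0.79 (SE 0.0984, edgeR adjusted p = 1.67e-05), BIRC3, an apoptosis inhibitor, by 0.73, TNFAIP2 by 0.68 and NFKB2, an NF-kappaB subunit, by 0.43. Cholesterol biosynthesis genes had 11 of 19 up and none down (13 and 0 adjusted over the list alone; mean 0.28), among them HMGCS1 (0.44), IDI1 (0.45), LSS (0.41), all enzymes of the pathway, and INSIG1 (0.50), its feedback regulator. Estrogen response genes had 7 of 29 up and none down (14 and 0 adjusted over the list alone; mean 0.16), with PGR, the progesterone receptor, at 0.91 and TFF1, a secreted trefoil factor, at 0.38. EGR3 was at 0.57 (adjusted p = 0.00703), lost without NC 3 (0.06). Nucleic acid sensing genes had 4 of 15 up and none down, both over all genes and adjusted over the list alone (mean 0.19), with SAMHD1, which breaks down nucleotides, at 0.43 and the RNA sensors IFIH1 at 0.30 and RIGI at 0.34. MHC class II genes had 1 of 8 up (3 adjusted over the list alone; mean 0.45), which was CD74, the invariant chain, at 0.72 (adjusted p = 0.0195), lost without NC 3 (0.124) or CYFIP1 knockout 1 (0.0582) or 3 (0.0743). Interferon ligands, receptors and kinases had 1 of 13 up (2 adjusted over the list alone; mean 0.37), the kinase JAK2 at 0.44. p53 targets had 1 of 28 up (9 adjusted over the list alone; mean 0.12, adjusted p = 0.0682 with an estimated correlation), CDKN1A, a cell cycle inhibitor, at 0.30 (adjusted p = 0.0147), lost without NC 2 (0.136), NC 3 (0.0863) or CYFIP1 knockout 1 (0.0639). The unfolded protein and integrated stress response list had 2 of 19 up (6 up and 1 down adjusted over the list alone; mean 0.17, adjusted p = 0.108 with an estimated correlation), with ATF3, a stress-induced transcription factor, at 0.47.

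The largest falls in the CYFIP1 knockout under the same limits, after CYFIP1 itself, included those of BMF, a pro-apoptotic BCL2-family gene (-0.90, SE 0.132, edgeR adjusted p = 0.000241), the keratin KRT80 (-0.60), CDCA7L (-0.59) and NMNAT1, an enzyme of NAD synthesis (-0.58). ALDH1A3, which makes retinoic acid, was at -0.73 (adjusted p = 0.0124), lost without NC 2 (0.1), NC 3 (0.0766) or CYFIP1 knockout 1 (0.0551) or 3 (0.0667). ID1, an inhibitor of differentiation factors, was at -0.56 (0.0279), lost without NC 2 (0.208), NC 3 (0.116) or CYFIP1 knockout 2 (0.0886) or 3 (0.0922). PGM5 was at -0.64 (0.0322), lost without NC 2 (0.0826), NC 3 (0.348) or CYFIP1 knockout 1, 2 or 3 (0.131, 0.0554 and 0.0574). MUC1, a luminal surface mucin, rose by 0.38, the only call among 18 luminal genes, also adjusted over the list alone (mean 0.00). No list mean passed the test for cell cycle and replication (0.02), luminal genes (median -0.02), basal genes (0.12, median -0.03), SRF and YAP targets (0.06, median -0.02, camera leaning down), epithelial-mesenchymal transition (0.01), the WAVE and Arp2/3 complexes (-0.13, but median -0.00 and mean -0.00 over the 18 members other than CYFIP1) or phosphoinositide enzymes (0.03). Nor did it for hypoxia and glycolysis (-0.10), checkpoint and NK ligands (0.08), histones (0.08), mitochondrially encoded genes (-0.03), immune cell markers (0.04, median -0.02) or fibroblast and endothelial markers (-0.03, median 0.01). CD68, a lysosomal protein used as a macrophage marker, was the only immune cell marker called of 4, higher by 0.49 (edgeR adjusted p = 0.0242), and was lost without NC 2 (0.214), NC 3 (0.111) or CYFIP1 knockout 1 (0.113). Among basal genes KRT17 was called, at 0.68 (0.0286), lost without NC 2 (0.193), NC 3 (0.235) or CYFIP1 knockout 1 (0.193), and among phosphoinositide enzymes INPP4B, at -0.30 (0.0076), lost without NC 2 (0.116) or NC 3 (0.0653). Without CYFIP1 knockout 1, hypoxia and glycolysis (-0.13, camera adjusted p = 0.0455) and mitochondrially encoded genes (-0.12, 0.0269) passed. Without CYFIP1 knockout 2 the cell cycle list passed at -0.06 (0.0213), and without CYFIP1 knockout 3 it passed at 0.09 (0.0084), as did mitochondrially encoded genes at 0.11 (0.00359) and checkpoint ligands at 0.14 (0.0269).

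In all, 289 of 20938 genes changed in the CYFIP1 knockout by edgeR, 216 higher and 73 lower, with a median absolute log2 fold change of 0.45 among them, and 2400 genes had an unadjusted p under 0.05. By camera, 11 of 24 lists passed, with adjusted p = 1.34e-58 for type I interferon-stimulated genes (0.00903 with an estimated correlation), 3.63e-20 for interferon-gamma response genes (0.00746) and 1.3e-12 for MHC class I (0.0119). The other calls were 9.09e-13 for NF-kappaB, 1.26e-13 for cholesterol biosynthesis, 1.6e-06 for estrogen response, 7.9e-06 for nucleic acid sensing, 1.48e-05 for MHC class II and 0.000632 for interferon ligands. With an estimated correlation these gave adjusted p = 0.0236, 0.0438, 0.0317, 0.00903, 0.00903 and 0.0243, and interferon ligands had 0.0617 with the stricter filter. The p53 targets had adjusted p = 4.43e-05, and adjusted p = 0.0682 with an estimated correlation. The stress response had adjusted p = 3.81e-05, and adjusted p = 0.108 with an estimated correlation or 0.227 with NC 4 as the only control. The count of 289 was 126 without NC 2, 122 without NC 3, 805 without NC 4 and 108 in a fit of these 2 groups alone. Another division of the same libraries, CYFIP1 knockout 1 and 2 with NC 4 against the rest, gave 1077 genes, of which 19 were among the 289 and 6 were type I interferon-stimulated genes.

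The NCKAP1 knockout also had higher interferon-stimulated genes, and genes of cholesterol biosynthesis and the progesterone receptor gene were also higher than in NC. RSAD2 stood at 4.51 ± 0.574 CPM against 1.54 ± 0.266 CPM in NC (SD, n = 3 each), a fold of 2.93, and IFIT3 at 382 ± 14.4 against 179 ± 26.3 CPM. PGR, a target of the estrogen receptor, stood at 31.9 ± 2.16 against 12.8 ± 0.991 CPM. IDI1, an isomerase of the cholesterol pathway, stood at 56.0 ± 1.91 against 27.3 ± 1.94 CPM. Of the 54 type I interferon-stimulated genes 44 rose and none fell (46 and 0 adjusted over the list alone; mean log2 fold change 0.59), and of the 22 MHC class I genes 8 rose and none fell (16 and 0; mean 0.42).

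Under the limits of expression and overlap given above, the largest rises were RSAD2 (log2 fold change 1.55, SE 0.159, edgeR adjusted p = 2.2e-07), SAMD9L (1.52), TRIM22 (1.45), MX2 (1.35), PGR (1.32), IFIT2 (1.18), TRANK1 (1.14) and APOL6 (1.13). In the type I list, IFIT3 rose by 1.10, SAMD9 by 1.06, OASL by 1.04, IFIT1 by 0.74, ISG15 by 0.60 and OAS1 by 0.46, while IRF9 was at -0.05 (adjusted p = 0.706). STAT1 was at 0.24 (0.0185), lost without NC 2 (0.0753), NC 3 (0.104) or NCKAP1 knockout 2 (0.0739) or 3 (0.0623). MX1 was at 0.30 (0.017), lost without NC 2 (0.0701), NC 3 (0.0715) or NCKAP1 knockout 3 (0.0825). Interferon-gamma response genes had 8 of 20 up and none down (12 up and 1 down adjusted over the list alone; mean 0.59), with APOL1 at 1.05, GBP3 at 1.01 and APOL2 at 0.45, while IRF1 at 0.24 (0.1; 0.31 and 0.0407 without NC 4) did not pass. In the MHC class I list, B2M rose by 0.52 (SE 0.06, edgeR adjusted p = 1.61e-06), from 86.4 ± 1.58 to 124 ± 2.67 CPM, NLRC5 by 1.36, PSME2, a proteasome activator, by 0.37 and PDIA3, a chaperone of peptide loading, by 0.28. TAP1 was at 0.38 (0.00537), lost without NC 2 (0.0667). HLA-A was at 0.61 (0.0287), lost without NC 2 (0.148), NC 3 (0.0966) or NCKAP1 knockout 2 (0.18) or 3 (0.0988). HLA-B was at 0.89 (0.0402), lost without any of the 6 libraries: NC 2 (0.0753), NC 3 (0.0824), NC 4 (0.121), NCKAP1 knockout 1 (0.131), 2 (0.0937) or 3 (0.0708). HLA-C at 0.42 (0.226) did not pass.

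Cholesterol biosynthesis genes had 17 of 19 up and none down in the NCKAP1 knockout (18 and 0 adjusted over the list alone; mean 0.56), with IDI1 at 1.04 (SE 0.0758, edgeR adjusted p = 4.74e-10), INSIG1 at 1.01, HMGCS1 at 0.73 and LDLR, the receptor for low-density lipoprotein, at 0.83. Cell cycle and replication genes had 8 of 26 up and none down (15 and 0; mean 0.20, adjusted p = 0.335 with an estimated correlation), including CDC6, which licenses replication origins (0.44), PCNA, the replication clamp (0.37), BUB1, a spindle checkpoint kinase (0.35), and CCNA2, cyclin A2 (0.30). Estrogen response genes had 11 of 29 up and 2 down (13 and 3; mean 0.15, adjusted p = 0.217 with an estimated correlation), with TFF1 at 0.51, the receptor kinase RET at 0.56 and SIAH2 at 0.39, while AREG, an EGF receptor ligand, fell (-0.46). Nucleic acid sensing genes had 6 of 15 up and 1 down, and the same counts adjusted over the list alone (mean 0.13), with IFIH1 at 0.42, SAMHD1 at 0.50, the kinase TBK1 at 0.39 and RIGI at 0.36. MAVS, the adaptor of RNA sensors, was at -0.27 (0.00972), lost without NC 2 (0.0663), NC 3 (0.0653) or NCKAP1 knockout 2 (0.0608). SRF and YAP targets had 4 of 21 down and none up, also adjusted over the list alone (mean -0.17, adjusted p = 0.512 with an estimated correlation), including the actin gene ACTG1 (-0.41), FLNA, an actin cross-linker (-0.41), and AJUBA, a scaffold at cell junctions (-0.64).

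At a mean log2-CPM of at least 2 and without overlap of libraries, the largest falls in the NCKAP1 knockout, after NCKAP1 itself, were those of KRT80 (-1.35, SE 0.0821, edgeR adjusted p = 3.26e-11), IGFBP5, an insulin-like growth factor-binding protein (-1.27), DIRC3-AS1 (-1.27), PGM5 (-1.23), ALDH1A3 (-1.18), C4orf19 (-1.10) and ID1 (-1.06). DIRC3-AS1 is an antisense RNA, whose counts are uncertain because the strand setting is not stated. MICA, a stress ligand of NK cells, rose by 0.77 and ULBP1, another such ligand, fell (-0.67), and the list of checkpoint and NK ligands did not pass (mean 0.10). CD68 rose from 6.09 ± 0.693 to 9.14 ± 0.674 CPM, a log2 fold change of 0.59 (0.00143), and the 4 immune cell markers measured did not pass as a list (0.04). FAS, a death receptor, rose by 0.49 among p53 targets (5 of 28 up, 6 up and 1 down adjusted over the list alone, mean 0.07), JAK2 by 0.52 among interferon ligands, receptors and kinases (2 of 13 up, 3 adjusted over the list alone, mean 0.31), and HSPA5, an endoplasmic reticulum chaperone, by 0.48 in the stress response (4 up and 2 down of 19, 7 and 3 adjusted over the list alone, mean 0.06, not past the test except without NC 4, with 0.11 and 0.00658). Among basal genes (mean 0.09), KRT17 rose by 1.00 and TP63 fell (-0.75), and among luminal genes (-0.05), KRT7 (-0.60) and ELF3 (-0.37) fell while MUC1 rose by 0.40. INPP4B, a phosphoinositide phosphatase, fell (-0.47) and PI4K2B rose by 0.29 (list mean 0.06). PFKFB3, a regulator of glycolysis, fell (-0.39) (hypoxia and glycolysis mean 0.01). The other lists that did not pass were MHC class II (0.22), NF-kappaB (-0.02, median 0.03, camera leaning up), the WAVE and Arp2/3 complexes (-0.15, but median -0.02 and mean 0.02 over the 18 members other than NCKAP1), epithelial-mesenchymal transition (0.08, median -0.00), histones (-0.09), mitochondrially encoded genes (0.08) and fibroblast and endothelial markers (0.09).

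By edgeR, 1688 genes changed in the NCKAP1 knockout, 880 higher and 808 lower, with a median absolute log2 fold change of 0.38. By camera, 8 lists passed, with adjusted p = 1.11e-37 for type I interferon-stimulated genes, 3.51e-10 for interferon-gamma response genes, 3.02e-09 for MHC class I, 8.45e-21 for cholesterol biosynthesis and 0.00111 for nucleic acid sensing. All 5 had adjusted p = 0.0293 with an estimated correlation. The cell cycle list had adjusted p = 1.15e-07, and adjusted p = 0.335 with an estimated correlation. Estrogen response had adjusted p = 0.00197, and adjusted p = 0.217 with an estimated correlation. The SRF and YAP list had adjusted p = 0.024, and adjusted p = 0.512 with an estimated correlation, and the call was also lost without NC 4 (mean -0.11, 0.172) or NCKAP1 knockout 1 (-0.13, 0.089). The count of 1688 was 792 without NC 2, 945 without NC 3, 1019 without NCKAP1 knockout 1 and 919 without NCKAP1 knockout 2.

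The PIP5K1A knockout had the most changed genes of the 3 and the largest means of the interferon and MHC class I lists. RSAD2 stood at 11.5 ± 0.672 CPM against 1.54 ± 0.266 CPM in NC (SD, n = 3 each), a fold of 7.45, and IFIT3 at 633 ± 25.4 against 179 ± 26.3 CPM. B2M stood at 153 ± 5.87 against 86.4 ± 1.58 CPM, a fold of 1.77, and TAP1 at 59.7 ± 2.74 against 24.5 ± 3.64 CPM, a fold of 2.44. Of the 54 type I interferon-stimulated genes 51 rose and none fell (52 and 0 adjusted over the list alone; mean log2 fold change 1.01), and of the 22 MHC class I genes 17 rose and none fell (18 and 0; mean 0.75). ATF4, the transcription factor of the integrated stress response, was lower, at 154 ± 7.96 against 276 ± 13.1 CPM.

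With the same limits (a mean log2-CPM of at least 2, no overlap of libraries), the largest rises were RSAD2 (log2 fold change 2.90, SE 0.15, edgeR adjusted p = 5.43e-14), SAMD9L (2.81), TGFB2-AS1 (2.79), TGFB2, a transforming growth factor beta ligand (2.697), GBP1 (2.54), TRIM22 (2.47), APOL6 (2.24) and TRANK1 (2.21). TGFB2-AS1 and SLC7A11-AS1 are antisense RNAs, with the strand setting not stated. In the type I list, SAMD9 rose by 1.96, IFIT3 by 1.83, IFIT2 by 1.70, IFIT1 by 1.25, ISG15 by 1.18, OAS1 by 0.98, STAT1 by 0.84 and MX1 by 0.53, while IRF9 was at -0.01 (adjusted p = 0.904). Interferon-gamma response genes had 16 of 20 up and none down (17 and 0 adjusted over the list alone; mean 1.21), with APOL1 at 1.74, APOL2 at 1.10 and IRF1 at 1.01. In the MHC class I list, NLRC5 rose by 2.05 (SE 0.231, edgeR adjusted p = 2e-07), HLA-B by 1.72, TAP1 by 1.29, B2M by 0.82, HLA-A by 0.65, HLA-E by 0.60 and PSME2 by 0.57. HLA-C was at 0.64 (0.0145), lost without NC 2 (0.105) or PIP5K1A knockout 2 (0.0658). MHC class II genes had 7 of 8 up and none down, also adjusted over the list alone (mean 0.83), among them CIITA, the class II transactivator (0.61), CD74 (1.01), HLA-DRB1 (1.21) and IFI30 (0.46). HLA-DRB1 was at only 0.462, 0.708 and 0.521 CPM in NC. Interferon ligands, receptors and kinases had 4 of 13 up (6 adjusted over the list alone; mean 0.47, adjusted p = 0.061 with an estimated correlation), including JAK1 (0.84), IFNGR1 (0.43) and IFNB1, interferon beta (1.62, SE 0.366). IFNB1 was near the floor, at 0.132, 0.303 and 0.365 CPM in NC and 0.814, 0.718 and 0.913 CPM in the PIP5K1A knockout, so its change is uncertain. Nucleic acid sensing genes had 9 of 15 up and 2 down, also adjusted over the list alone (mean 0.34), with IFIH1 at 0.76, SAMHD1 at 0.89, RIGI at 0.75 and IKBKE at 0.69. IRF3 was lower, at 82.9, 92.2 and 76.1 CPM against 104, 94.0 and 102 CPM in NC. STING1, near the floor, was at 0.197, 0.0239 and 0.203 CPM against 0.550, 0.632 and 0.182 CPM.

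NF-kappaB genes had 11 of 18 up and none down in the PIP5K1A knockout (12 and 0 adjusted over the list alone; mean 0.72, adjusted p = 0.0633 with an estimated correlation), including BIRC3 (1.24, SE 0.114, edgeR adjusted p = 5.72e-09), TNFAIP3 (1.07) and RELB, an NF-kappaB subunit, which rose from 8.72 ± 0.694 to 20.0 ± 1.12 CPM. The p53 targets had 18 of 28 up and none down (21 and 0; mean 0.40), with CDKN1A at 0.89, BTG2, an antiproliferative gene, at 0.80, TIGAR, which limits glycolysis, at 0.77 and FAS at 0.97. Cholesterol biosynthesis genes had 17 of 19 up and none down (17 and 0; mean 0.58, adjusted p = 0.0633 with an estimated correlation), with IDI1 at 1.33 and LSS at 0.82. Targets of SRF and YAP had 13 of 21 up and 2 down (15 and 3; mean 0.63, adjusted p = 0.191 with an estimated correlation), among them ACTA2, smooth muscle actin (1.12), FLNA (0.85) and ANKRD1, a YAP target (3.07, SE 0.342). ANKRD1 was at only 0.264, 0.303 and 0.886 CPM in NC. Basal genes had 6 of 11 up and 1 down (6 and 1; mean 0.57, adjusted p = 0.0633 with an estimated correlation), with KRT17 at 2.11, SFN at 0.72 and LAMC2, a laminin chain, at 1.14, while TP63 fell (-1.48). Checkpoint and NK ligands had 9 of 15 up and 1 down (10 and 1; mean 0.41, adjusted p = 0.0633 with an estimated correlation), including NECTIN2 (0.42), CD276 (0.37), MICB (1.51) and LGALS9 (1.55), while ULBP1 fell (-1.89). In NC, MICB was at only 0.661, 0.607 and 0.573 CPM and LGALS9 at 0.308, 0.303 and 0.443 CPM. Cell cycle genes had 12 of 26 up and 2 down (12 and 3; mean 0.17, adjusted p = 0.537 with an estimated correlation), including the cyclin E genes CCNE1 (0.70) and CCNE2 (0.68), while UBE2C, a mitotic ubiquitin-conjugating enzyme, fell (-0.31). Phosphoinositide enzymes had 9 of 27 up and 3 down (9 and 3; mean 0.12, or 0.18 over the 26 members other than PIP5K1A, adjusted p = 0.178 with an estimated correlation), with PIK3R3 at 1.04 and PIK3R1 at 0.68, both regulatory subunits of PI3-kinase, and PLCG1, which cleaves PI(4,5)P2, at -0.39. Histones had 8 of 11 up and none down (8 and 0; mean 0.56, adjusted p = 0.061 with an estimated correlation), with H1-2 at 0.80 and H2AC6 at 0.60. Mitochondrially encoded genes had 9 of 13 up and none down (9 and 0; mean 0.34, adjusted p = 0.439 with an estimated correlation), with MT-ND1 at 0.63, beside the higher mitochondrial share of counts given above (7.06% against 6.14%).

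Again at a mean log2-CPM of at least 2 and without overlap of libraries, the largest falls in the PIP5K1A knockout were KIF21B, a kinesin (-2.35, SE 0.235, edgeR adjusted p = 1.94e-06), NDRG1, a stress- and hypoxia-induced gene (-2.04), NCMAP (-2.01), ULBP1 (-1.89), INHBE (-1.85), PHGDH, which starts serine synthesis (-1.66), SLC7A11-AS1 (-1.62) and GRIK3 (-1.62). PIP5K1A itself fell less than these genes. In the stress response list, 9 of 19 genes were up and 7 down, and the same adjusted over the list alone, as in the next 5 lists unless given, and the list did not pass (mean -0.09, median 0.01). HSPA5 rose by 0.75, DNAJB9, a co-chaperone, by 0.71 and ATF3 by 0.79, while ATF4 (-0.84) and PSAT1, an enzyme of serine synthesis (-1.23), fell. Estrogen response genes had 12 of 29 up and 11 down (mean -0.05), with NRIP1, a receptor corepressor, at 0.60 and CCN5 at 0.76, and AREG at -1.27 and STC2 at -0.94. Hypoxia and glycolysis genes had 3 of 16 up and 6 down (4 and 6; mean -0.16), with ENO1, a glycolytic enzyme, at 0.50 and PDK1 at -1.07. Luminal genes had 7 of 18 up and 3 down (mean 0.15), with KRT7 at 0.69, KRT18 at 0.52 and GRHL2, an epithelial transcription factor, at -0.44. The WAVE and Arp2/3 list had 6 of 19 up and 1 down (mean 0.06), with the Arp2/3 subunits ACTR3 at 0.34 and ARPC2 at 0.26 and ABI2, a WAVE complex subunit, at -0.31. Epithelial-mesenchymal transition genes had 2 of 14 up and 1 down (mean 0.33), with SERPINE1 at 1.24 and CD44 at -0.56. Neither immune cell markers (mean 0.20, median -0.21, camera leaning up) nor fibroblast and endothelial markers (0.39) passed as lists, although ITGAM, a myeloid integrin, rose from 0.307 ± 0.138 to 1.12 ± 0.178 CPM.

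By edgeR, 6800 genes changed in the PIP5K1A knockout, 3474 higher and 3326 lower, with a median absolute log2 fold change of 0.43, and 887 of them changed at least 2-fold. By camera, 16 lists passed, with adjusted p = 9.29e-33 for type I interferon-stimulated genes (0.0317 with an estimated correlation), 3.75e-12 for interferon-gamma response genes (0.0212), 5.73e-10 for MHC class I (0.0235), 3.06e-05 for MHC class II (0.0212), 0.000185 for nucleic acid sensing (0.022) and 9.96e-10 for p53 targets (0.0235). The other calls were lost with an estimated correlation. NF-kappaB (3.59e-07), checkpoint ligands (0.00442), basal genes (0.00257) and cholesterol biosynthesis (1.42e-10) each had adjusted p = 0.0633 with an estimated correlation. Histones (0.000927) and interferon ligands (0.00615) each had adjusted p = 0.061 with an estimated correlation, and interferon ligands had 0.0781 with the stricter filter. For SRF and YAP targets (0.000185), camera had adjusted p = 0.191 with an estimated correlation, mitochondrially encoded genes (0.00114) adjusted p = 0.439 and cell cycle (0.0104) adjusted p = 0.537. Phosphoinositide enzymes (0.0398) had adjusted p = 0.178 with an estimated correlation, and were lost without NC 4 (0.0882) or PIP5K1A knockout 1 (0.0685). Over the 6 contrasts, camera called 66 lists, of which 42 were lost with an estimated correlation, and in 38 of these 42 that was the highest adjusted p under any alternative.

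**Figure D2:**
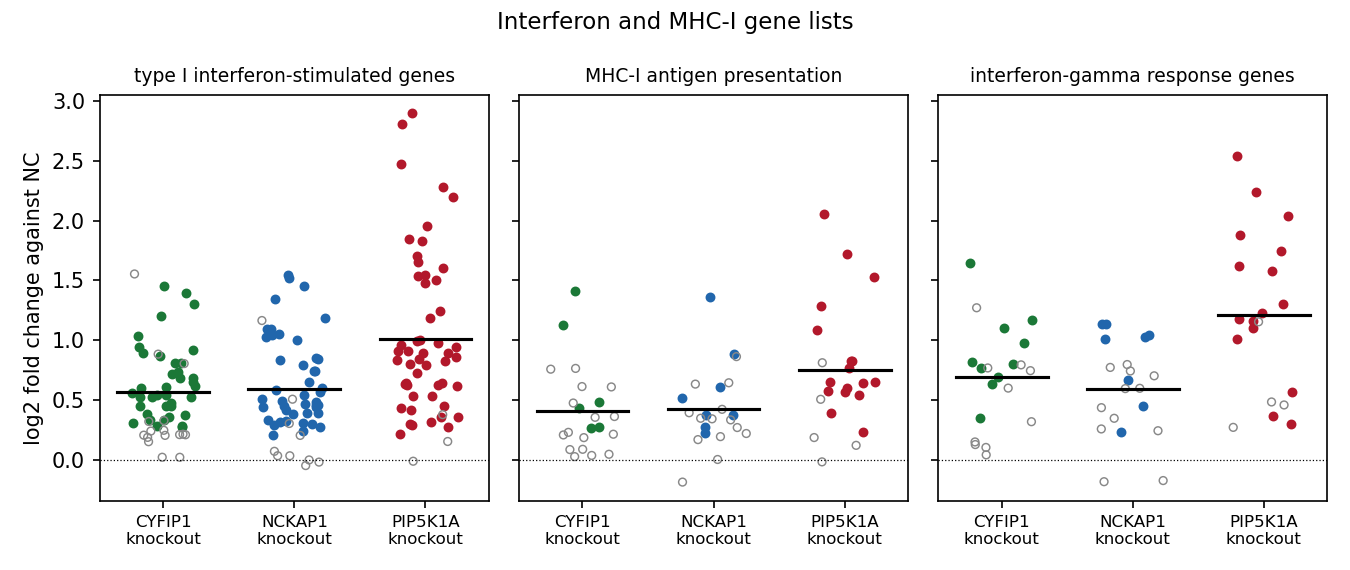
Log2 fold change against NC of each measured member of the type I interferon-stimulated, MHC class I and interferon-gamma response lists in the 3 knockouts (filled points, edgeR adjusted p under 0.05; grey open points, not past it; lines, list means). The means are 0.57, 0.41 and 0.69 in the CYFIP1 knockout, 0.59, 0.42 and 0.59 in the NCKAP1 knockout and 1.01, 0.75 and 1.21 in the PIP5K1A knockout.

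**Figure D3:**
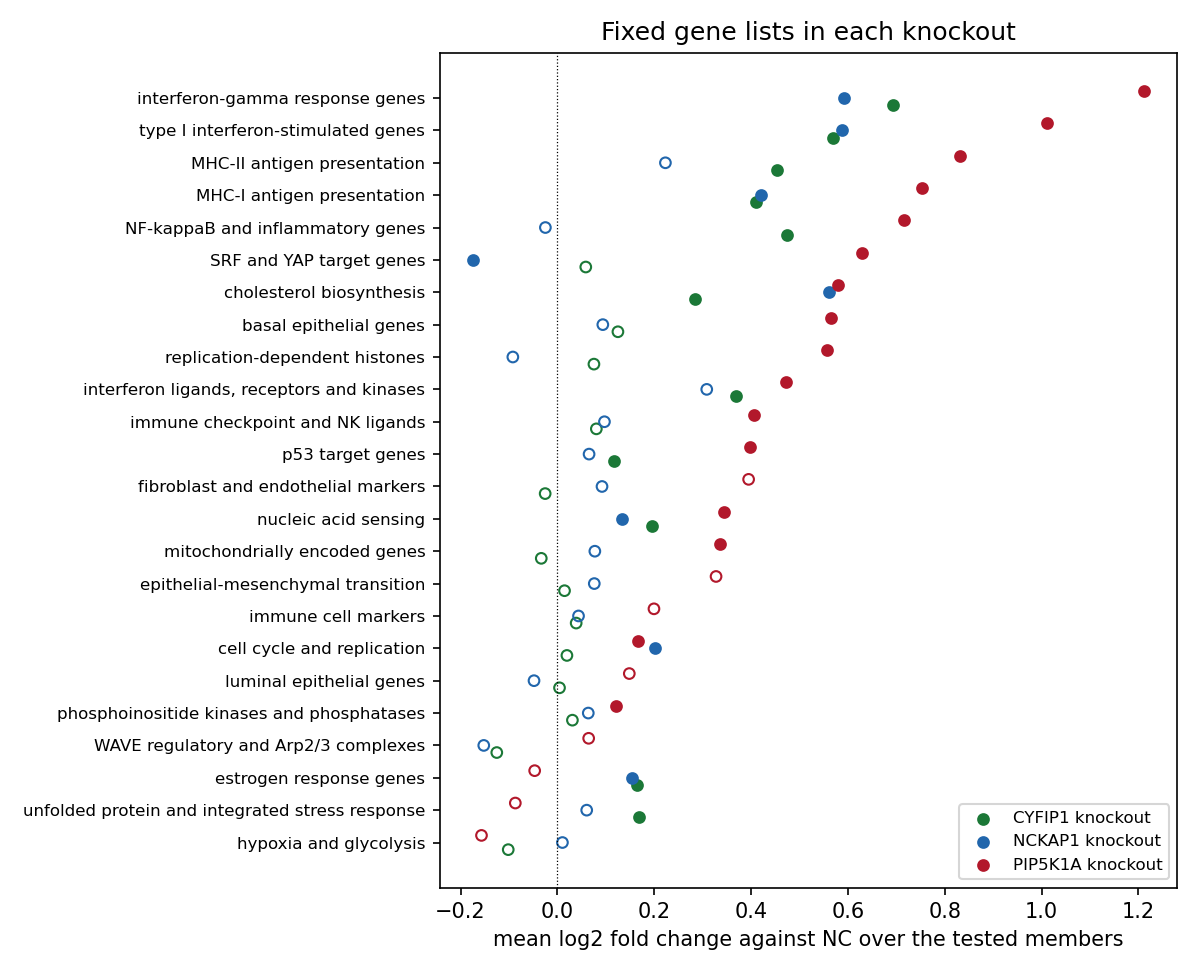
Mean log2 fold change against NC of each of the 24 gene lists in the 3 knockouts (filled, camera adjusted p under 0.05; open, not past it). Camera passed 11 lists in the CYFIP1 knockout, 8 in the NCKAP1 knockout and 16 in the PIP5K1A knockout.

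Between the CYFIP1 and NCKAP1 knockouts, which target subunits of the same complex, no difference was called in the interferon and MHC class I lists as wholes, while NF-kappaB genes were higher and cholesterol and cell cycle genes lower in the CYFIP1 knockout at camera's preset correlation. These 3 calls were lost, with adjusted p = 0.315, 0.315 and 0.568 with an estimated correlation. Here and in the following contrasts, values are the knockout named first minus the other. Type I interferon-stimulated genes differed by a mean of -0.02 (2 higher and 4 lower of 54, 3 and 5 adjusted over the list alone, camera adjusted p = 0.374), MHC class I genes by -0.01 (0.711) and interferon-gamma response genes by 0.10 (0.425). TNFAIP3 was at 25.5 ± 3.44 CPM in the CYFIP1 and 14.6 ± 0.159 CPM in the NCKAP1 knockout (SD, n = 3 each), and IDI1 at 37.3 ± 4.56 against 56.0 ± 1.91 CPM. NF-kappaB genes had 6 of 18 higher and none lower (8 and 0 adjusted over the list alone; mean 0.50, camera adjusted p = 2.27e-08). Cholesterol genes had 10 of 19 lower and none higher (15 and 0; mean -0.28, 1.2e-10). Cell cycle genes had 5 of 26 lower and none higher (12 and 0; mean -0.18, 8.99e-08). SRF and YAP targets had 3 of 21 higher (4 adjusted over the list alone; mean 0.23, 0.00756), with adjusted p = 0.74 with an estimated correlation and 0.0944 without CYFIP1 knockout 1. Of the single genes, SERPINA3, a protease inhibitor, was higher by 1.40 (SE 0.141, edgeR adjusted p = 4.31e-06), and SLC26A10P, a pseudogene (-0.72), and the antisense RNA IDI2-AS1 (-0.69) were lower. INHBE was at 0.96 (0.00998), lost without NCKAP1 knockout 1 (0.0555) or 2 (0.0501). KIF21B was at 0.96 (0.0172), lost without CYFIP1 knockout 1 (0.0591) or 3 (0.0571) or NCKAP1 knockout 1 (0.0666). FAM111B was at -0.70 (0.033), lost without CYFIP1 knockout 3 (0.12) or NCKAP1 knockout 1, 2 or 3 (0.128, 0.109 and 0.0505). By edgeR 798 genes differed, 401 higher and 397 lower, with CYFIP1 at -2.30 and NCKAP1 at 3.23, and the count was 344 without CYFIP1 knockout 1, 1216 without CYFIP1 knockout 2, 511 without CYFIP1 knockout 3, 230 without NCKAP1 knockout 1 and 217 without NCKAP1 knockout 2.

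The CYFIP1 knockout had lower interferon-stimulated, MHC class I, p53 target and cholesterol genes than the PIP5K1A knockout at camera's preset correlation. These 4 calls were lost, with adjusted p = 0.168, 0.16, 0.0995 and 0.213 with an estimated correlation. Type I interferon-stimulated genes had 35 of 54 lower and 1 higher (39 and 1 adjusted over the list alone; mean -0.44, camera adjusted p = 2.21e-13). MHC class I genes had 10 of 22 lower and 1 higher (11 and 1; mean -0.34, 0.000261). B2M was at 104 ± 5.79 against 153 ± 5.87 CPM and RSAD2 at 3.54 ± 0.522 against 11.5 ± 0.672 CPM (SD, n = 3 each). Interferon-gamma response genes (mean -0.52, 7.65e-05), p53 targets (-0.28, 2.3e-06), MHC class II genes (-0.38, 0.00942), basal genes (-0.44, 0.00224), histones (-0.48, 0.00253) and nucleic acid sensing (-0.15, 0.0119) also passed, each with adjusted p = 0.0995 with an estimated correlation. Cholesterol genes (mean -0.30, 7.65e-05) and SRF and YAP targets (-0.57, 0.000261) passed, each with adjusted p = 0.213 with an estimated correlation. Estrogen response genes were higher, 15 of 29 up and 8 down, also adjusted over the list alone (mean 0.21, 0.00648), with adjusted p = 0.204 with an estimated correlation. Mitochondrially encoded genes were lower, 10 of 13 by both adjustments (mean -0.37, 0.000261), with adjusted p = 0.374 with an estimated correlation. Checkpoint and NK ligands (mean -0.33, 0.0316) had adjusted p = 0.204 with an estimated correlation and 0.206 with the stricter filter, and were lost without PIP5K1A knockout 1 (0.0787). The cell cycle list (mean -0.15, 0.0227) had adjusted p = 0.532 with an estimated correlation and was lost without CYFIP1 knockout 3 (0.236). Of the single genes, KIF21B (2.57, SE 0.234, edgeR adjusted p = 9.09e-07), INHBE (1.85), SLC7A11-AS1 (1.82) and ULBP1 (1.79) were higher, and TGFB2-AS1 (-3.15), TGFB2 (-3.10), CYFIP1 (-2.51) and ALDH1A3 (-2.42) were lower. By edgeR 6075 genes differed, 2889 higher and 3186 lower.

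The NCKAP1 knockout also had lower interferon-stimulated and MHC class I genes than the PIP5K1A knockout by camera at its preset correlation. Type I interferon-stimulated genes had 40 of 54 lower and 1 higher (41 and 2 adjusted over the list alone; mean -0.42, camera adjusted p = 1.49e-15), and MHC class I genes 13 of 22 lower and none higher (13 and 1; mean -0.33, 0.000223), both with adjusted p = 0.111 with an estimated correlation. TRIM22 was at 19.0 ± 1.42 against 38.7 ± 1.93 CPM and CDKN1A at 66.7 ± 2.65 against 109 ± 4.47 CPM (SD, n = 3 each). Interferon-gamma response genes (mean -0.62, 1.7e-07), p53 targets (-0.33, 2.41e-09), MHC class II genes (-0.61, 8.2e-05) and histones (-0.65, 3.58e-05) each had adjusted p = 0.0458 with an estimated correlation. NF-kappaB genes had 11 of 18 lower and 1 higher (13 and 1; mean -0.74, 1.67e-07), with adjusted p = 0.0771 with an estimated correlation. SRF and YAP targets had 13 of 21 lower and 1 higher (15 and 1; mean -0.80, 2.08e-07), with adjusted p = 0.111 with an estimated correlation, and FLNA was at 311 ± 16.0 against 741 ± 15.1 CPM. Estrogen response genes had 15 of 29 higher and 5 lower (16 and 6; mean 0.20, 0.00109), also with adjusted p = 0.111 with an estimated correlation. Basal genes (-0.47, 0.000807) had adjusted p = 0.0572, nucleic acid sensing (-0.21, 0.00456) adjusted p = 0.0555 and mitochondrially encoded genes (-0.26, 0.0021) adjusted p = 0.444 with an estimated correlation. Checkpoint and NK ligands (-0.31, 0.0335) had adjusted p = 0.155 with an estimated correlation and 0.237 with the stricter filter, and were lost without PIP5K1A knockout 1 (0.101). Cholesterol genes did not differ as a list (mean -0.02, 0.853). Of the single genes, KIF21B (1.61), SLC7A11-AS1 (1.60), SLC7A11, a cystine transporter (1.59, SE 0.0705, edgeR adjusted p = 2.43e-15), and the antisense RNA APOA1-AS (1.49) were higher, and TGFB2-AS1 (-3.62), TGFB2 (-3.55), NCKAP1 (-3.34) and ALDH1A3 (-2.87) were lower. CYFIP1 was at -0.21 (0.0222), lost without NCKAP1 knockout 1, 2 or 3 (0.0712, 0.0543 and 0.085) or PIP5K1A knockout 2 or 3 (0.12 and 0.0725). By edgeR 4592 genes differed, 2217 higher and 2375 lower.

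Interferon-stimulated genes led the genes changed in the same direction in all 3 knockouts against NC. Among those at a mean log2-CPM of at least 2, the 8 with the largest smallest change were TRIM22, SAMD9L, MX2, RSAD2, APOL6, OAS2, GBP3 and IFIT3, all higher. In all 3 knockouts 115 genes were higher and 21 lower, where 1.51 and 0.447 would be shared by independent lists. The CYFIP1 and NCKAP1 knockouts shared 203 genes in the same direction (156 higher, 47 lower) and 2 in opposite directions, where 11.9 in the same direction would be shared by independent lists. The CYFIP1 and PIP5K1A knockouts shared 178 (150 higher, 28 lower) and 29 opposite, with 47.4 for independent lists. The NCKAP1 and PIP5K1A knockouts shared 1071 (601 higher, 470 lower) and 98 opposite, with 274 for independent lists. Simulated groups without any difference, compared with the same simulated NC, shared 0, 0 and 0.05 genes on average. These simulations called at most 5 genes in a contrast, so that almost none could be shared. They also drew genes independently, without any structure of the samples, and so set no chance level for the shared counts. Across genes, which are not independent replicates, the 2 log2 fold changes had a Pearson correlation of 0.539, 0.398 and 0.475 in the 3 pairs, against 0.499, 0.497 and 0.494 in the simulations, and so below these in 2 of 3 pairs. Their covariance was 0.0543, 0.0604 and 0.0850, against 0.0282, 0.0280 and 0.0279 in the simulations, or 0.0344, 0.0341 and 0.0341 scaled to the residual variance of the data. The share of this overlap that comes from the common NC libraries was not separated. The count for the CYFIP1 and NCKAP1 knockouts was 91 without NC 2, 90 without NC 3 and 506 without NC 4, and that for the CYFIP1 and PIP5K1A knockouts 87, 88 and 540. That for the NCKAP1 and PIP5K1A knockouts was 475 without NC 2, 586 without NC 3, 664 without NCKAP1 knockout 1 and 606 without NCKAP1 knockout 2.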

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

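The tests of explanations in this part were chosen after the results were seen, and the matching of genes for the check of GC content was widened after a first run; the other splits of the libraries were planned. In 8 cases a list had means of opposite sign against NC in 2 knockouts and differed between these by camera at its preset correlation. NF-kappaB genes differed by 0.50 between the CYFIP1 and NCKAP1 knockouts (0.47 and -0.02 against NC), with adjusted p = 0.315 with an estimated correlation. NF-kappaB genes also differed by -0.74 between the NCKAP1 and PIP5K1A knockouts (adjusted p = 0.0771 with an estimated correlation). SRF and YAP targets differed by 0.23 between the CYFIP1 and NCKAP1 knockouts (0.06 and -0.17 against NC), with adjusted p = 0.74 with an estimated correlation and a call that was lost without CYFIP1 knockout 1 (0.0944). SRF and YAP targets also differed by -0.80 between the NCKAP1 and PIP5K1A knockouts (-0.17 and 0.63 against NC; adjusted p = 0.111 with an estimated correlation). Estrogen response genes differed by 0.21 between the CYFIP1 and PIP5K1A knockouts (0.16 and -0.05 against NC; adjusted p = 0.204 with an estimated correlation). They differed by 0.20 between the NCKAP1 and PIP5K1A knockouts (adjusted p = 0.111 with an estimated correlation). Mitochondrially encoded genes differed by -0.37 between the CYFIP1 and PIP5K1A knockouts (adjusted p = 0.374 with an estimated correlation). Replication-dependent histones differed by -0.65 between the NCKAP1 and PIP5K1A knockouts (-0.09 and 0.56 against NC; adjusted p = 0.0458 with an estimated correlation).

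Interferon-stimulated genes were higher in all 3 knockouts than in NC. A difference of NC 2 and NC 3 from NC 4 was argued against as the whole cause, since at least 79.5% of the mean log2 fold change was kept with NC 4 as the only control. Trends with GC content and gene length were also argued against as the whole cause, since at least 98.9% was kept with these removed. A low level in the NC culture alone would raise all 3 knockouts alike, while 35 of the 54 genes were higher in the PIP5K1A than in the CYFIP1 knockout. That difference covers only the part of the PIP5K1A rise beyond the CYFIP1 rise (means of 1.01 and 0.57 against NC). Its camera call as a list was lost with an estimated correlation (adjusted p = 0.168). Between the CYFIP1 and NCKAP1 knockouts, 6 of the 54 genes differed. For the part of the rise common to all 3 knockouts, a low NC level and an effect of the knockouts cannot be told apart. All comparisons with NC use the same 3 NC libraries.

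The PIP5K1A knockout changed more genes than the other knockouts, 6800 against 289 and 1688. Trends with GC content and gene length were argued against as the whole cause, as 6709 genes were called with these removed. A smaller spread between the PIP5K1A replicates is also argued against, as the SD of log2 fold changes less their error was 1.88 times that of the NCKAP1 knockout. A larger effect of this knockout on expression may therefore be a candidate explanation, and a difference in culture or infection that coincides with the group stays open.

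CYFIP1 knockout 1 and 2 with NC 4 differed from CYFIP1 knockout 3 with NC 2 and NC 3 by 1077 genes (628 higher and 449 lower), more than the 289 of the real comparison, which points to a structure of the samples other than the groups. Of 22 mitochondrial tRNA genes 12 were called higher on the first side, with MT-TW at 0.61, while MCM5 was at 0.42 and the noncoding RNA LINC00342 at -0.52. Trends with GC content and gene length are argued against as the whole cause, since 801 genes were called with these removed, against 1042 of the 1077 for which GC content was known. The amount of small noncoding RNA kept in the libraries may contribute and stays open. Of the tested genes of the GENCODE classes snRNA, snoRNA, scaRNA and misc_RNA, 26.8% were higher on the first side, and 5 of 213 were called, all lower. The labels name no batch, and no biological explanation was tested.

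A comparison of 3 libraries against 3 has only 10 splits, too few for a share under 0.05. Of the 10 splits of the CYFIP1 and NC libraries, 2 gave at least 289 genes, and the highest other count was 1077. In the other 5 comparisons only the real split, 1 of 10, gave as many genes (1688, 6800, 798, 6075 and 4592), and the highest other count was 0. The real mean of type I interferon-stimulated genes was 0.57, 0.59 and 1.01 in the CYFIP1, NCKAP1 and PIP5K1A knockouts, and the largest of another split was 0.33, 0.28 and 0.39. For MHC class I these were 0.41, 0.42 and 0.75 against 0.26, 0.18 and 0.30, and for interferon-gamma response genes 0.69, 0.59 and 1.21 against 0.36, 0.28 and 0.43. Each other split puts 2 libraries of 1 group with 1 of the other, which lowers its mean by design where the groups differ. The size of these gaps therefore does not measure the strength of a result.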

How the results depend on the processing

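The halved counts, the RN7SK covariate, NC 4 as the only control, no mitochondrial genes, the GC and length offsets and protein-coding genes only were chosen after the data were seen. The calls of the targeted genes in their own knockouts and of the type I interferon-stimulated, MHC class I and interferon-gamma lists against NC held under every alternative run. Without single libraries the list means were 0.53 to 0.64, 0.36 to 0.46 and 0.63 to 0.75 in the CYFIP1 knockout, 0.55 to 0.65, 0.40 to 0.45 and 0.56 to 0.64 in the NCKAP1 knockout and 0.97 to 1.08, 0.73 to 0.78 and 1.17 to 1.26 in the PIP5K1A knockout. Counts of changed genes moved more. Fitting only the 2 groups gave 108 for CYFIP1 against NC (289), 482 for CYFIP1 against NCKAP1 (798) and 5656 for CYFIP1 against PIP5K1A (6075). CYFIP1 then shared 85 genes with NCKAP1 (203) and 82 with PIP5K1A (178). The contrasts without CYFIP1 rose, to 1861 for NCKAP1 against NC (1688), 7334 for PIP5K1A against NC (6800) and 6096 between them (4592). Fewer libraries alone therefore do not account for the falls. The median SD of log2-CPM between replicates was 0.111 in the CYFIP1 knockout, 0.0905 in NC, 0.0791 in the NCKAP1 and 0.067 in the PIP5K1A knockout. NC 4 as the only control gave 23, 317 and 2783 changed genes (289, 1688 and 6800) and 20, 18 and 182 shared genes (203, 178 and 1071), with the lone library assumed to vary like the others. A change of at least 2-fold, a stricter threshold, gave 19, 140, 887, 32, 708 and 568 genes in the 6 contrasts and 12, 13 and 54 shared genes. With the replicate number as a block, CYFIP1 against NC had 552 genes, and CYFIP1 shared 376 and 385 genes with NCKAP1 and PIP5K1A. NC 4 is the only library numbered 4, so its block term fitted it and the NC level rested on NC 2 and NC 3. The block therefore acts much like leaving out NC 4 and is no test of pairing alone. Libraries of the same number in different groups correlated at -0.271 to 0.170 after group means were removed, so the numbers showed no pairing. Those of different numbers correlated at -0.348 to 0.328, with 14 of 39 pairs over 0.1 and 10 under -0.1. The highest were CYFIP1 knockout 3 with NCKAP1 knockout 1 (0.328) and with NC 2 (0.317), and NC 4 with NCKAP1 knockout 3 was at 0.279. A structure across groups other than the numbers therefore stays open, also for the NCKAP1 libraries. Without single libraries the counts were 122 to 805, 792 to 2123 and 5091 to 6868 against NC, 217 to 1216, 4512 to 5739 and 3231 to 3713 between knockouts, and 90 to 506, 87 to 540 and 475 to 1490 for shared genes; the lowest and highest against NC for CYFIP1 were without NC 3 and NC 4. With an estimated correlation camera passed, outside the type I interferon, interferon-gamma and MHC class I lists, 2 lists instead of 5 for NCKAP1 and 3 instead of 13 for PIP5K1A against NC. Of all 24 lists, it passed 0 instead of 4, 0 instead of 14 and 4 instead of 13 in the contrasts between knockouts. Lists called between CYFIP1 and NCKAP1 were 4 to 7 without single libraries. In the CYFIP1 knockout 3 lists that had not passed turned sign and passed: cell cycle (0.02) at -0.062 with NC 4 as the only control and -0.064 to 0.085 without single libraries, SRF and YAP targets (0.06) at -0.059 with NC 4 as the only control, and mitochondrially encoded genes (-0.03) at -0.12 to 0.11 without single libraries. Apart from the stricter threshold and the lone block of NC 4, the cause of these moves was not tested. Over 312 results for named genes, 334 of 5552 alternatives ended a call, 113 of them with NC 4 as the only control, and 8 made one. Over 144 list results, 81 of 2922 ended a call, 42 of them with an estimated correlation, and 61 made one. HLA-A, HLA-B, HLA-C and NLRC5 had group means of only 0.828 to 4.47 CPM, which limits their precision. IFNB1, ANKRD1, MICB, LGALS9 and HLA-DRB1 were also near the floor in NC, with the same limit.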

Other observations

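The genes of this and the next paragraph and the test of the chromosome arms were chosen after values were seen, and the position of the largest step along the chromosomes of NCKAP1 and PIP5K1A was added, and how to weigh it settled, after the percentiles were known. Several genes, picked by the size of the opposite changes, moved in opposite directions in the NCKAP1 and PIP5K1A knockouts. ALDH1A3, which makes retinoic acid, was at -1.18 on the log2 scale in the NCKAP1 and 1.70 in the PIP5K1A knockout (n = 3 each, edgeR adjusted p of the difference = 2.03e-13), and TGFB2 at -0.85 and 2.697 (4.28e-19). MYO1B, a membrane-bound myosin, was at -0.71 and 1.07 (6.7e-17), BCAS1 at -0.73 and 0.92 (2.9e-15), PGM5, which is found at cell junctions, at -1.23 and 1.10 (2.75e-11) and GPRC5A, a retinoic acid-induced receptor, at -0.75 and 0.78 (5.31e-12).

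CYP1A1, a target of the aryl hydrocarbon receptor, was at -0.70 in the NCKAP1, -0.48 in the CYFIP1 and 0.69 in the PIP5K1A knockout, and BCAS1 was at -0.45 in the CYFIP1 knockout. SERPINA3, an acute-phase protease inhibitor, was at 0.68 in the CYFIP1 and 0.74 in the PIP5K1A knockout but -0.72 in the NCKAP1 knockout. IGF2, a growth factor, was at 0.53 in the CYFIP1 and -0.95 in the PIP5K1A knockout (edgeR adjusted p of the difference = 1.19e-08).

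CRISPR breaks may remove the chromosome arm beyond the target in part of the cells, and this was weighed as a hypothesis that stayed open for all 3 targets. Beyond CYFIP1, 431 genes had a median log2 fold change of -0.08 in the CYFIP1 knockout, at percentile 0 (on a scale of 0 to 100) of stretches of as many genes elsewhere, which ran from -0.02 to 0.03. For all 3 targets, such stretches were moved by 1 gene at a time along the other chromosomes long enough to hold them. Neighboring stretches overlap almost wholly, so few are independent and the percentiles are not p-values. The fall was not shown to start at the target, since only 4 genes lie before it, with a median of -0.11, and no step was sought there. The same genes were also low in the PIP5K1A knockout, at -0.03, where CYFIP1 was not targeted (libraries at -0.0233, -0.0524 and -0.0313, against -0.1005, -0.0717 and -0.0861 in the CYFIP1 knockout). Beyond NCKAP1, 219 genes had a median of -0.10 in the NCKAP1 knockout, also at percentile 0 (lowest other -0.05), but the largest step along the chromosome lay 19.3 Mb and 66 genes from the target. Beyond PIP5K1A, 458 genes had a median of -0.02 in the PIP5K1A knockout, at percentile 0.950, against -0.00 and 0.03 in the CYFIP1 and NCKAP1 knockouts. Its libraries were at -0.0311, -0.0318 and 0.00064, so that 1 of 3 was not lower, CYFIP1 knockout 3 was at -0.0267, and the largest step lay 34.4 Mb and 95 genes before the target.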
